A study of Danio rerio with 24 samples.

How the data were processed

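Expression was measured by RNA sequencing of total RNA from whole wild-type zebrafish embryos. The 24 libraries fall into 6 groups of 4: embryos in 0.1% dimethyl sulfoxide (DMSO) with 0 or 40 µM tetrabromobisphenol A (TBBPA), exposed from 0.75 hours post fertilization (hpf) and collected at 2, 3.5 or 4.5 hpf, per the labels' protocols. The library protocol in the labels names both a directional and a non-directional kit, so whether the libraries kept the strand is not known. Overlapping and antisense genes are therefore read as uncertain.

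The deposited values are FPKM (fragments per kilobase of gene length, scaled to the size of the library), per the file headers and the labels, in 2 tables of 31901 genes, 1 for the 8 libraries of 2 hpf and 1 for the 16 libraries of 3.5 and 4.5 hpf. Each value column was assigned to its sample through the description in the labels, and 0 value columns stayed unassigned. Reads were aligned with HISAT2 2.0.5 and assigned to genes with featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build and the annotation release are not given in the sources used here. Gene symbols, identifiers, positions and gene types (25431 genes are annotated as protein coding) were taken from the tables themselves, and positions are printed as the tables give them. Symbols of 8 list members that the tables do not use were matched through a table that pairs Ensembl identifiers with symbols.

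The deposited FPKM multiplied by the gene length gave whole multiples of 1 step in each library for 100% of genes within 0.001 of a step. Within each table the inverse of the step was proportional to the median-of-ratios size factor computed over the libraries of that table. The authors' FPKM were therefore scaled separately in each table, and levels at 2 hpf are set beside those of 3.5 and 4.5 hpf without a test. The multiples were taken as the reads assigned to each gene and summed to 10.6 to 20.0 M (mega) reads per library. The 36 pairs of replicates had Pearson correlations of 0.991 to 0.997 on log2(FPKM+1), and their squared differences exceeded Poisson counting noise 2.64 to 15.6 times, pooled over genes. The pairs with DMSO replicate 4 at 2 hpf lay at 14.4 to 15.6, against 5.71 to 7.49 for the other pairs of that group.

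The following choices were made before the data were examined, unless stated otherwise. Genes with at least 1 FPKM in at least 4 libraries of a fit were kept. Each comparison used limma 3.58.1 in R 4.3.3 (linear models with moderated variances that follow a trend with expression) on log2(FPKM+1), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. TBBPA was compared with DMSO at each time, and 4.5 hpf with 3.5 hpf within each treatment, with 4 libraries against 4. The difference between the TBBPA effects at 4.5 and 3.5 hpf was the interaction of treatment and time over the 16 libraries of the shared table. A pseudocount of 1 pulls log2 differences of genes near or under 1 FPKM toward 0, so printed differences of weakly expressed genes understate their ratio of means. Means are given with the standard deviation (SD) between the 4 libraries of a group.

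Genes were placed in 3 classes without regard to treatment, from these same libraries. Zygotic-only genes had a mean under 0.5 FPKM over the 8 libraries of 2 hpf and at least 2 FPKM over the 8 libraries of 4.5 hpf (655 genes). Maternal genes had a mean of at least 2 FPKM at 2 hpf and were called falling where the mean at 4.5 hpf was at most 0.667 times that at 3.5 hpf (774 genes) and stable otherwise (8805 genes). These levels were set across the separately scaled tables. In addition, 27 gene lists were fixed from general knowledge. They held early zygotic genes, activators of the zygotic genome, acetyltransferases, deacetylases, histone and DNA methylation enzymes, oocyte-deposited transcripts and maternal clearance factors. Others held germ plasm, markers of the embryonic cell layers and axes, and stress, receptor and metabolic pathways. The rest held cell cycle, transcription machinery, ribosomal proteins, mitochondrially encoded genes, and markers of cell types absent at these stages. Classes and lists with at least 3 tested genes were tested with limma's camera, which compares a set with the other genes under a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a set move 1 way on balance. Adjustment was over the lists, or the classes, of a comparison. Some genes are on several lists, so the list results are not independent. The list counts are given over all genes tested and adjusted over the list alone.

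The named genes follow a fixed rule. For each TBBPA comparison they are the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 5 FPKM in 1 of the groups, no overlap between the libraries of the groups, and a symbol that is not a clone or locus name. For the interaction, where overlap was not asked, and for the changes over time they are the 5 largest each way. Up to 4 members of each list with the smallest p were added, and pou5f3, nanog, sox19b, ep300a, ep300b, crebbpa, crebbpb, hdac1, klf17, vox, cyp1a and buc were included whatever their values. Some genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

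For each library 8 measures were computed, among them the share of summed FPKM in zygotic-only genes and in maternal falling genes, and the share of recovered reads in mitochondrially encoded genes. TBBPA and DMSO were compared with a 2-sided exact permutation test over the 70 assignments of 4 against 4 libraries, whose smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the 24 tests. Correlations and slopes across genes are descriptions, since genes are not independent replicates.

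The alternatives were other pseudocounts and filters, median-of-ratios, TPM and total-count scaling, leaving out each library in turn, the replicate number as a block, library weights, no variance trend, 1 fit over 16 libraries, and other limits for the zygotic class. Total-count scaling and limma voom on the recovered reads were added after the data were seen. On simulated counts drawn from the means and depths of the real libraries with a set of changed genes, the 4.5 hpf fit recovered 59.7%, 82.8% and 97.0% of changes of 1.5-fold, 2-fold and 4-fold among 12298 genes, with 5.42% false calls. The 3.5 hpf fit recovered 71.2%, 92.3% and 100% among 11889 genes, with 5.98% false calls. The 2 hpf fit recovered 47.0%, 77.3% and 96.9% among 11009 genes, with 2.04% false calls. The simulated sets gave 147, 184 and 166 called genes at 2, 3.5 and 4.5 hpf, against 0, 1424 and 8392 in the real fits. The adjusted threshold depends on how many genes change, so the recovered shares do not carry over to the real fits. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. No library was left out.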

Results

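Wild-type zebrafish embryos were exposed to 40 µM TBBPA, a brominated flame retardant, or to the vehicle DMSO alone, from 0.75 hpf until collection at 2, 3.5 or 4.5 hpf. These stages run from the cleavage period, when embryos rely on maternal transcripts, across the onset of zygotic transcription. RNA levels were measured in 24 whole-embryo libraries, 4 for each treatment and time, and are given below as mean FPKM ± SD with n = 4 per group. Where TBBPA is set against DMSO at the same time, a rise or fall means a higher or lower level in TBBPA. It does not mean a change over time. By the title of the series, the exposure was studied for its effects on zygotic transcription and histone acetylation, and the comparisons asked which transcripts differed between exposed and vehicle embryos at each stage. Reads assigned to genes, as recovered from the values, averaged 13.6 ± 0.30 M (mega, SD) in TBBPA and 13.4 ± 0.47 M in DMSO at 2 hpf, 16.1 ± 1.8 and 13.7 ± 2.1 M at 3.5 hpf, and 15.7 ± 1.5 and 15.5 ± 3.7 M at 4.5 hpf. These totals gave exact permutation p = 0.486, 0.114 and 0.971 (2-sided, n = 4 per group). The labels do not state whether the replicates came from separate clutches or exposures, so the p-values measure the spread between these samples.

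At 2 hpf the maternal transcripts of the activators of the zygotic genome were abundant in both groups. Nanog lay at 1052 ± 41 FPKM in TBBPA and 1133 ± 52 in DMSO, pou5f3 at 691 ± 21 and 735 ± 25, and sox19b at 433 ± 8.7 and 436 ± 18. The acetyltransferase gene ep300b lay at 48.8 ± 3.0 and 46.9 ± 4.5 FPKM, and the deacetylase gene hdac1 at 151 ± 8.9 and 163 ± 3.6. The ventralizing gene vox, a zygotic transcript, was listed at 0 in all 8 libraries. Zygotic-only genes took 0.0223% ± 0.0016 of summed FPKM in TBBPA and 0.0227% ± 0.00086 in DMSO, a difference smaller than the spread between replicates (exact permutation p = 0.743, n = 4 per group).

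No gene passed the threshold at 2 hpf: limma called 0 of 11061 tested genes, and limma voom on the recovered reads called 0. At an unadjusted p under 0.05 limma gave 795 genes, where chance alone gives 553.05, and the smallest adjusted p was 0.434. For 98.3% of the genes the 95% confidence interval excluded a 2-fold difference. None of the 18 lists with at least 3 tested genes held a gene past the threshold. Ribosomal protein genes (74 tested, median log2 difference −0.10) and mitochondrially encoded genes (13 tested, median −0.18) lay lower than other genes by camera, with adjusted p = 3.79e-07 and 2.52e-06. Both calls were lost with an estimated correlation (adjusted p = 0.385 for each), and fry gave adjusted p = 0.232 and 0.258. The mitochondrial share of reads did not differ at 2 hpf (exact permutation p = 0.257, n = 4 per group). It was highest in DMSO replicate 4 (2.77%, against 2.21% to 2.47% in the other DMSO libraries), which also stood apart on the first principal component (29.3, against −5.99 to −0.83 in the other 7 libraries). Adjusted over the list alone, 1 acetyltransferase gene passed, naa10, with a log2 difference of −1.12 (chosen after its values were seen).

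By 3.5 hpf, genes of the p53 response had risen in exposed embryos. The growth arrest gene gadd45aa (ENSDARG00000043581, chromosome 2, 10280645 to 10284572; the build is not stated) lay at 15.9 ± 0.72 FPKM in TBBPA and 1.06 ± 0.58 in DMSO, a log2 difference of 3.07 (SE 0.15). The cyclin-dependent kinase inhibitor gene cdkn1a (ENSDARG00000076554, chromosome 22, 603382 to 607812) lay at 30.8 ± 1.4 and 4.39 ± 1.03. The pro-apoptotic gene bbc3 lay at 7.74 ± 0.65 and 1.0 ± 0.46, and phlda3, a p53 target that restrains Akt, at 9.61 ± 2.1 and 0.789 ± 0.49. Of 20 tested members of the list of p53 targets and apoptosis genes, 9 rose, 1 fell and 10 did not pass the threshold (11 higher and 3 lower adjusted over the list alone). The median log2 difference of the list was 0.13 and its camera adjusted p 3.2e-05, and the call was lost with an estimated correlation (adjusted p = 0.157).

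**Figure D1:**
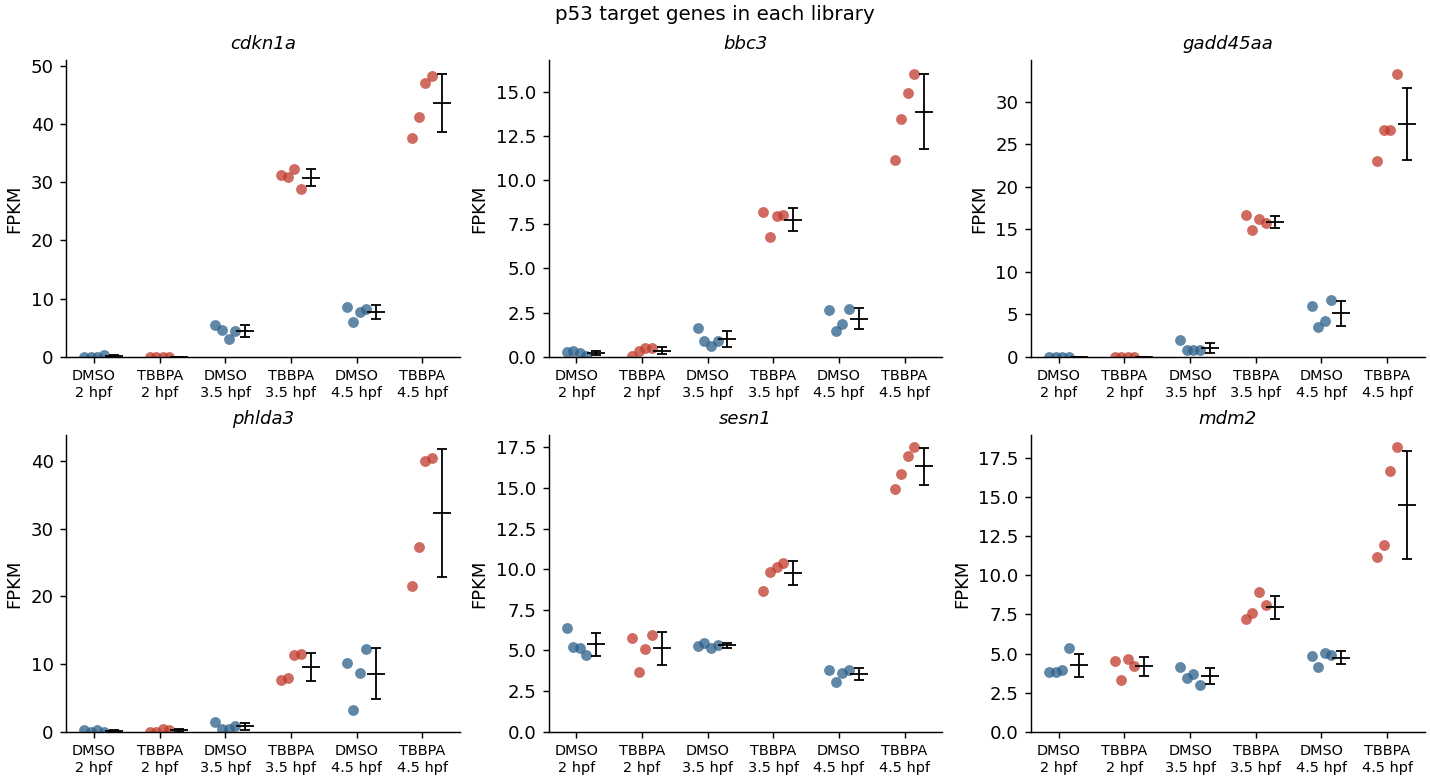
FPKM of the p53 target genes cdkn1a, bbc3, gadd45aa, phlda3, sesn1 and mdm2 in each library (points), with the mean and SD of the 4 libraries of each group, for DMSO (blue) and TBBPA (red) at each time. At 4.5 hpf cdkn1a had a mean of 43.6 FPKM in TBBPA and 7.60 in DMSO.

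The other large rises at 3.5 hpf were in the immediate-early genes fosab (7.80 ± 0.76 against 0.765 ± 0.24 FPKM) and jun (9.96 ± 0.35 against 2.41 ± 0.45), the ubiquitin-like gene isg15 (25.7 ± 5.2 against 4.10 ± 1.3), the apelin receptor gene aplnrb (175 ± 24 against 39.5 ± 2.4), with rasl11b (log2 difference 2.10) and plekhn1 (1.68). The largest falls included genes of the enveloping layer, the outer epithelium of the blastula. The claudin gene cldne lay at 1.48 ± 0.53 FPKM in TBBPA and 11.7 ± 1.7 in DMSO, and grhl3, an epithelial transcription factor gene, at 7.40 ± 1.2 and 27.2 ± 1.9. The transcription factor genes foxd3 (3.84 ± 0.95 against 16.2 ± 0.75) and tfap2a (1.71 ± 0.47 against 8.17 ± 0.73) also fell, with sult6b1 (log2 difference −2.04), ftr82 (−1.80), ackr3b (−1.60) and net1 (−1.59). The histone genes hist1h2a4 (−1.78) and hist2h3c (−1.67) fell, but histone genes have near-identical copies among which reads may have been divided, so their single values are uncertain. All of these genes had limma adjusted p of 3.8e-04 or less. The rule that named them asked for no overlap between the libraries of the groups.

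In total 1424 of 11859 tested genes passed the threshold at 3.5 hpf (limma), 791 higher and 633 lower in TBBPA (943 and 566 with TPM, 889 and 585 with total-count and 704 and 692 with median-of-ratios scaling), and 16 of the higher and 116 of the lower ones differed by more than 2-fold. The libraries of the groups did not overlap for 17.2% of genes, against 2.86% by chance. Without TBBPA replicate 2 at 3.5 hpf the count was 925.

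Zygotic genes as a class were lower and cleared maternal transcripts higher in exposed embryos at 3.5 hpf. Of 458 tested zygotic-only genes 221 fell and 18 rose (260 and 23 adjusted over the list alone), with a median log2 difference of −0.52. Of 763 maternal falling genes 269 rose and 1 fell (380 and 5 adjusted over the list alone), with a median of 0.17. In contrast 483 of 8727 maternal stable genes rose and 326 fell (595 and 262 with TPM scaling), with a median of 0.01. With an estimated correlation, camera gave adjusted p = 0.0225 for the zygotic-only and 0.0346 for the maternal falling class. Zygotic-only genes took 0.671% ± 0.080 of summed FPKM in TBBPA and 1.01% ± 0.029 in DMSO, with all 4 TBBPA libraries below all 4 DMSO libraries. Maternal falling genes took 5.58% ± 0.23 and 4.77% ± 0.053, with all 4 TBBPA libraries above. Both differences had exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and adjusted p = 0.049 over 24 tests.

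**Figure D2:**
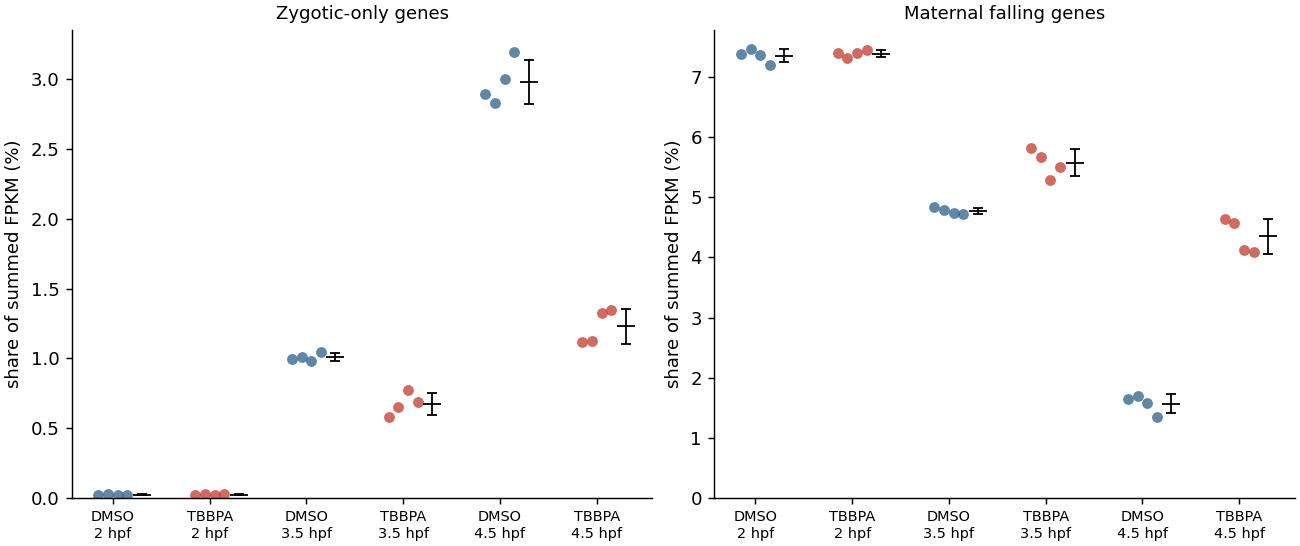
Percent of summed FPKM in zygotic-only genes (left) and maternal falling genes (right) in each library (points), with the mean and SD of the 4 libraries of each group, for DMSO (blue) and TBBPA (red). At 4.5 hpf the zygotic-only share averaged 1.23% in TBBPA and 2.98% in DMSO, and the maternal falling share 4.36% and 1.57%.

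Among the fixed lists at 3.5 hpf, neurectoderm markers fell in 5 of 9 tested genes (9 of 9 adjusted over the list alone; camera adjusted p = 3.94e-09), for example sox3 (48.4 ± 5.9 against 102 ± 2.5 FPKM) and sox19a (7.94 ± 1.1 against 18.8 ± 2.4). Ventral and BMP pathway genes fell in 8 and rose in 1 of 15 (10 and 3 adjusted over the list alone; 2.02e-05), with gata3 at 8.11 ± 1.5 against 20.3 ± 0.89. Early zygotic genes fell in 10 and rose in 4 of 22 (12 and 4 adjusted over the list alone; 0.000191), with klf17 at 99.8 ± 12 against 191 ± 4.7 and nnr at 50.1 ± 7.5 against 120 ± 2.5. Vox lay at 18.9 ± 0.57 against 17.9 ± 0.57 and did not pass. Dorsal organizer genes fell in 4 of 8 (0.00301; chrd 0.618 ± 0.17 against 2.68 ± 0.18). Enveloping layer markers fell in 3 of 5 (0.0109) and endoderm markers in 2 of 3 (0.0165; cxcr4a 39.3 ± 6.8 against 78.7 ± 2.2), with the same counts adjusted over the list alone. Mesoderm and Nodal genes fell in 5 and rose in 1, aplnrb, of 11 (6 and 2 adjusted over the list alone; 0.0192). These calls were lost with an estimated correlation, with adjusted p = 0.157 for the neurectoderm, dorsal and enveloping layer lists, 0.193 for the ventral list, 0.239 for the endoderm and mesoderm lists, and 0.323 for the early zygotic list.

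Activators of the zygotic genome and acetyl-lysine readers fell in 4 of 10 tested genes at 3.5 hpf (4 lower and 1 higher adjusted over the list alone): the bromodomain gene brd2a (41.9 ± 3.1 against 61.8 ± 0.90 FPKM), hmga1a, pou5f3 (461 ± 11 against 518 ± 3.6) and nanog (907 ± 17 against 984 ± 8.6). The list had camera adjusted p = 0.0109, and adjusted p = 0.315 with an estimated correlation. Sox19b lay at 477 ± 20 and 445 ± 7.5 (adjusted p = 0.0545). It passed with TPM scaling (adjusted p = 0.0194), with total-count scaling (0.0404), and without TBBPA replicate 3 (0.0252) or 4 (0.0452). The acetyltransferase and deacetylase genes mostly did not pass. The acetyltransferase list also holds naa10, naa50, esco1 and esco2, whose products act mainly on proteins other than histones. Clockb was the 1 of 19 acetyltransferase genes that rose (19.6 ± 0.98 against 15.5 ± 0.73), and 3 rose with TPM and 2 with total-count scaling. Among 16 deacetylase genes 1 of the 2 genes with the symbol hdac8 rose and hdac9b fell, with the same counts adjusted over the list alone. Ep300b lay at 29.6 ± 6.2 and 36.4 ± 2.2 (adjusted p = 0.116), and without TBBPA replicate 4 at 3.5 hpf its log2 difference moved from −0.31 to −0.44 and passed (0.00112). Crebbpa, crebbpb and hdac1 did not pass (adjusted p = 0.134, 0.809 and 0.188), and ep300a, with means of 0.453 and 0.555 FPKM, was below the filter. Of 26 genes for histone and DNA methylation enzymes 2 rose, dnmt1 (223 ± 8.1 against 177 ± 2.9) and kdm4ab, and setd2 fell (3 higher and 2 lower adjusted over the list alone).

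Oocyte-deposited transcripts rose in 7 and fell in 1 of 18 genes at 3.5 hpf (9 and 1 adjusted over the list alone; camera adjusted p = 0.000471, 0.315 with an estimated correlation), among them the Balbiani body gene buc (241 ± 22 against 184 ± 4.7 FPKM) and the translational regulator gene cpeb1b (119 ± 6.8 against 85.9 ± 2.1). Germ plasm genes rose in 3 of 12 (5 higher and 1 lower adjusted over the list alone), including tdrd6. Maternal clearance factors fell in 2 of 22, ythdf2 and elavl1a (2 adjusted over the list alone; camera adjusted p = 0.0192, 0.239 with an estimated correlation and 0.0582 with total-count scaling). Mitochondrially encoded genes fell in 12 of 13 (12 adjusted over the list alone; camera adjusted p = 6.81e-13, 0.157 with an estimated correlation), and their share of reads was 1.82% ± 0.10 in TBBPA and 2.14% ± 0.13 in DMSO (exact permutation p = 0.0286, n = 4 per group; adjusted p = 0.049). Ribosomal protein genes fell in 8 of 75 (8 adjusted over the list alone; 7.79e-08, 0.315 with an estimated correlation).

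The remaining lists were not called by camera at 3.5 hpf. Heat shock and unfolded protein response genes rose in 2 and fell in 3 of 16, with the small heat shock gene hspb1 at 24 ± 4.0 against 46.1 ± 4.2 FPKM. Cell cycle genes rose in 2 and fell in 3 of 31, and transcription machinery genes rose in 4 of 33 (5 higher and 1 lower adjusted over the list alone). Glycolysis genes rose in 3 and fell in 4 of 17 (5 and 5 adjusted over the list alone), and antioxidant genes rose in 3 of 15, for example txnrd3 (5 adjusted over the list alone). Thyroid, PPAR and estrogen receptor genes rose in 1 of 10, thraa (1 higher and 2 lower adjusted over the list alone), and none of 6 xenobiotic response genes passed. Cyp1a, a target of the aryl hydrocarbon receptor, had means of 0.780 FPKM in TBBPA and 0.787 in DMSO and was below the filter. Medians, means and test directions differed in sign for acetyltransferase, thyroid, glycolysis and xenobiotic genes and the maternal stable class, whose medians and means all lay from −0.0204 to 0.0176.

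At 4.5 hpf keratin and claudin genes were among the 10 largest falls in exposed embryos. The keratin genes krt92 (ENSDARG00000036834, chromosome 19, 5349656 to 5352199) and krt4 lay at 0.215 ± 0.031 and 0.460 ± 0.24 FPKM in TBBPA against 24.9 ± 7.3 and 23.6 ± 3.7 in DMSO, and the claudin genes cldne and cldnb at 5.03 ± 1.5 and 1.52 ± 0.77 against 109 ± 13 and 40.6 ± 5.9. The log2 differences of these 4 genes ranged from −4.38 to −4.08. Chrd, the dorsal BMP antagonist, lay at 3.14 ± 1.2 against 50.0 ± 8.8, and vox at 17.4 ± 1.1 against 80.8 ± 15. Several maternal transcripts were higher in TBBPA than in DMSO: sox19b (ENSDARG00000040266, chromosome 7, 26494583 to 26497947) at 325 ± 32 against 74.9 ± 11 FPKM, buc at 182 ± 12 against 48.0 ± 6.9, and cpeb1b at 88.0 ± 10.1 against 18.1 ± 0.95, with log2 differences of 2.11, 1.91 and 2.22.

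The other falls among the 10 largest at 4.5 hpf were in spaca4l (log2 difference −4.33, the second largest), chrd (−3.66), hist1h2a4 (−3.85, uncertain for its near-identical copies), stm (−3.63), alcamb (−3.60) and capn9 (−3.59), and further rises in dnajc5ga (2.62), cdkn1a (2.38), the buc paralog buc2l (2.28), bbc3 (2.25), gadd45aa (2.24), isg15 (2.06), lrrcc1 (2.04) and lsm1 (2.04), each with adjusted p of 1.8e-06 or less in limma. In all, 8392 of 12324 tested genes passed, 4075 higher and 4317 lower, of which 540 and 916 differed by more than 2-fold. The groups did not overlap for 63.4% of genes, against 2.86% by chance. The split depended on the scaling. There 5406 were higher and 2772 lower with TPM, and 5097 and 3022 with total-count scaling, which raised the median of all genes by 0.15 and 0.12 on the log2 scale.

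Of 654 tested zygotic-only genes 548 fell and 25 rose at 4.5 hpf (550 and 29 adjusted over the list alone; median log2 difference −1.42), and of 739 maternal falling genes 729 rose and none fell (730 higher adjusted over the list alone; median 1.03). With an estimated correlation camera gave adjusted p = 0.0472 for both classes. Maternal stable genes divided into 2990 higher and 2984 lower of 8714, with a median of −0.01 that turned to 0.15 with TPM and 0.12 with total-count scaling. The zygotic-only share of summed FPKM was 1.23% ± 0.12 in TBBPA and 2.98% ± 0.16 in DMSO, and 521 ± 29 zygotic-only genes reached 1 FPKM in TBBPA against 650.0 ± 1.8 in DMSO. The maternal falling share was 4.36% ± 0.29 in TBBPA and 1.57% ± 0.16 in DMSO. In each of these measures no TBBPA library overlapped the DMSO libraries (exact permutation p = 0.0286, n = 4 per group; adjusted p = 0.049).

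Markers of every embryonic layer on the fixed lists were mostly lower at 4.5 hpf. The lists share members, such as noto (early zygotic and dorsal) and gata6 (endoderm and yolk syncytial layer), so their results are not independent. Enveloping layer markers fell in 9 of 9 tested genes (camera adjusted p = 5.97e-05), endoderm markers in 7 of 7 (0.000994; foxa3 6.32 ± 2.0 against 39.7 ± 5.6 FPKM), and yolk syncytial layer markers in 4 of 4 (0.0238; gata6 1.53 ± 0.74 against 16.5 ± 5.8). Neurectoderm markers fell in 7 of 8 (0.00111; zic2b 2.89 ± 0.34 against 14.7 ± 0.83). Ventral and BMP pathway genes fell in 14 and rose in 3 of 17 (0.000717; tfap2a 5.77 ± 1.7 against 37.5 ± 1.1), mesoderm and Nodal genes fell in 11 and rose in 2 of 14 (0.00361; lft1 1.97 ± 0.51 against 16.8 ± 1.9). Dorsal organizer genes fell in 6 and rose in 1 of 9 (0.0377; noto 15 ± 5.1 against 96.7 ± 14). Early zygotic genes fell in 19 and rose in 3 of 23 (6.25e-05), with klf17 at 90.2 ± 7.2 against 135 ± 6.5. Against this direction stood aplnrb, on the early zygotic and mesoderm lists, at 380 ± 41 against 95.5 ± 9.1. The counts were the same adjusted over the list alone, and for each of these lists the call was lost with an estimated correlation (adjusted p = 0.318). With TPM or total-count scaling 6 endoderm, 10 mesoderm and 5 dorsal genes fell, and the other counts of falling genes did not move.

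**Figure D3:**
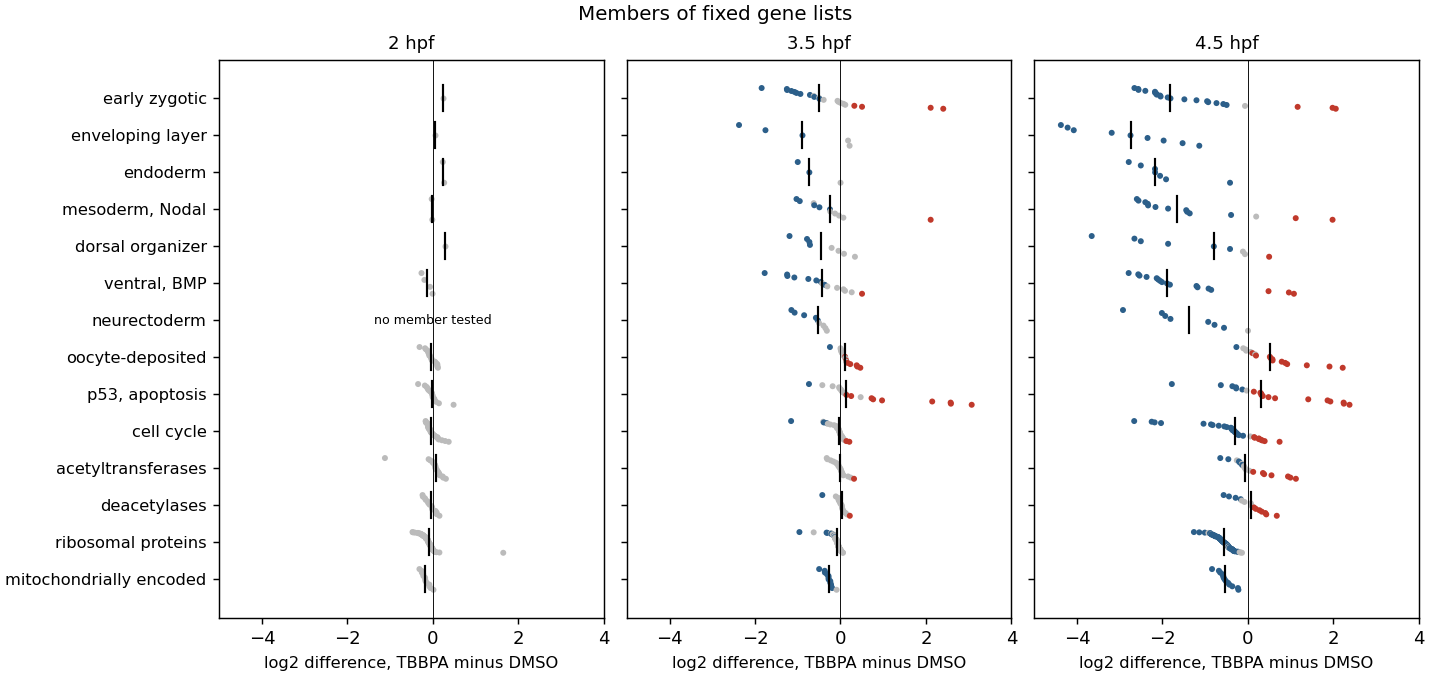
Log2 difference between TBBPA and DMSO of each tested member of 14 of the 27 fixed lists at each time (points; red higher, blue lower, grey not past the threshold), with the list median as a bar. At 4.5 hpf all 9 enveloping layer markers were lower with the deposited, TPM and total-count scaling, while the acetyltransferase median turned from −0.07 to 0.10 with TPM and 0.07 with total-count scaling.

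Oocyte-deposited transcripts rose in 12 and fell in 1 of 18 genes at 4.5 hpf (camera adjusted p = 0.000994; fbxo43 90.8 ± 9.6 against 34.2 ± 2.7 FPKM). Ribosomal protein genes fell in 68 of 75 (4.94e-15; median log2 difference −0.56; rpsa 42.7 ± 2.4 against 74.2 ± 2.3) and mitochondrially encoded genes in 13 of 13 (0.000124; median −0.54; mt-cyb 1780.2 ± 149 against 2843 ± 54), and with TPM or total-count scaling in 66 and 11. The mitochondrial share of reads was 1.85% ± 0.12 in TBBPA and 2.47% ± 0.060 in DMSO (exact permutation p = 0.0286, n = 4 per group; adjusted p = 0.049). The shares of reads in genes annotated as rRNA, mitochondrial ones included, and in the 10 genes with the most reads were also lower, at 0.0292% against 0.0447% and 3.27% against 4.73%, as they were at 3.5 hpf (0.0315% against 0.0380% and 3.11% against 3.27%; the same p for each). Cell cycle genes fell in 23 and rose in 8 of 32 (0.00361; 19 and 9 with TPM or total-count scaling), including the replication helicase gene mcm3 (12.0 ± 1.2 against 52.4 ± 6.2) and the cyclin genes ccnd1 (25.1 ± 5.7 against 162 ± 16) and ccne2. These 4 list calls were lost with an estimated correlation (adjusted p = 0.318), and the counts were the same adjusted over the list alone.

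The p53 targets cdkn1a, bbc3, gadd45aa, phlda3, mdm2 and sesn1 were higher at 4.5 hpf as well as at 3.5 hpf, with sesn1, a stress-induced regulator of growth, at 16.3 ± 1.1 against 3.55 ± 0.35 FPKM. Of 20 list members 13 rose and 6 fell (the same adjusted over the list alone), and the list did not pass by camera (adjusted p = 0.0635). Among those that fell was gadd45ba (11.7 ± 1.8 against 42.5 ± 3.5). Further p53 targets and apoptosis genes were lower too (chosen after their values were seen). These were pmaip1 (log2 difference −0.63), apaf1 (−0.36), ccng1 (−0.28) and baxa (−0.13), so the p53 targets did not move 1 way. Heat shock and unfolded protein response genes fell in 11 and rose in 4 of 17 (the same adjusted over the list alone; 0.0635, and 0.0499 with total-count scaling), with hspb1 at 75.3 ± 14 against 391 ± 51 and the disulfide isomerase gene pdia4 at 80.5 ± 4.4 against 33.5 ± 3.1.

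The acetyltransferase and deacetylase genes moved both ways at 4.5 hpf. Of 19 acetyltransferase genes 7 rose, including crebbpa (4.52 ± 0.45 against 1.87 ± 0.13 FPKM), kat6b and clockb, and 5 fell (2 with TPM or total-count scaling). Crebbpb (8.82 ± 0.33 against 9.83 ± 0.73) and ep300b (32.9 ± 4.1 against 33.8 ± 1.1) did not pass, and their differences changed sign with TPM scaling. Ep300a, with means of 0.566 and 0.321 FPKM, was below the filter, as was cyp1a (0.532 and 0.585). Of 16 deacetylase genes 7 rose and 4 fell, and 9 rose and 3 fell with TPM or total-count scaling. Hdac1 was lower in TBBPA, at 148 ± 3.8 against 201 ± 6.5. Of 26 methylation enzyme genes 8 rose, among them the demethylase gene kdm4ab (47.8 ± 4.3 against 11.6 ± 0.88) and the maintenance DNA methyltransferase gene dnmt1 (207 ± 14 against 87.4 ± 4.1), and 9 fell (12 and 4 with TPM). Of the activators of the zygotic genome and acetyl-lysine readers, 3 were higher in TBBPA, including sox19b and brd2b (25.2 ± 1.6 against 14.5 ± 1.3), and 6 of 10 were lower, including brd2a (54.3 ± 2.7 against 152 ± 3.5), pou5f3 (494 ± 8.9 against 843 ± 41) and nanog (971 ± 21 against 1346 ± 20).

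None of these lists was called by camera at 4.5 hpf, and neither were those below. The counts were the same adjusted over the list alone except for the activators (4 higher), germ plasm (6 higher) and glycolysis (7 higher). Maternal clearance factors fell in 14 and rose in 6 of 22, including ybx1 (446 ± 11 against 810.1 ± 47). Germ plasm genes rose in 5 and fell in 5 of 12 (7 and 1 with TPM). Transcription machinery genes rose in 8 and fell in 16 of 33, with the oocyte TBP paralog tbpl2 at 13.2 ± 1.0 against 4.15 ± 0.28. Antioxidant genes rose in 5, including sod1, and fell in 5 of 15, and glycolysis genes rose in 6 and fell in 7 of 17 (9 and 5 with TPM, 9 and 6 with total-count scaling). Thyroid, PPAR and estrogen receptor genes rose in 3 and fell in 2 of 10 (5 and 2 with TPM or total-count scaling), and xenobiotic response genes rose in 3 and fell in 1, tiparp, of 6. Of the markers of blood, immune, muscle and nerve cells, rag2 (2.88 ± 0.095 against 2.71 ± 0.12) and syt1a (1.51 ± 0.14 against 1.0 ± 0.12, adjusted p = 0.00649) passed the expression filter, too few for a set test. With TPM the transcription machinery had 13 higher and 12 lower genes, the antioxidant list 8 and 2, and the clearance list 7 and 10. With TPM or total-count scaling the medians of the acetyltransferase, methylation and antioxidant lists turned from negative (−0.07, −0.06 and −0.06) to positive. With the deposited scaling the means of these 3 lists (0.11, 0.13 and 0.13) already differed in sign from their medians, as did those of the maternal stable class (0.03) and the xenobiotic list (−0.0022).

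The comparison of 4.5 with 3.5 hpf in DMSO describes the normal change over this stage. Stm, a gene of otolith formation, rose from 1.58 ± 0.27 to 115 ± 23 FPKM, krt92 from 0.0954 ± 0.10 to 24.9 ± 7.3, and krt97, cdk5r1a and ca9 rose by 4.42, 4.28 and 4.27 on the log2 scale. Sox19b fell from 445 ± 7.5 to 74.9 ± 11, cpeb1b from 85.9 ± 2.1 to 18.1 ± 0.95 and dnajc5ga from 67.0 ± 4.3 to 7.52 ± 0.24, with papd7 (log2 change −2.27) and fam193a (−2.24). Of the genes fixed by name, vox rose from 17.9 ± 0.57 to 80.8 ± 15, pou5f3 from 518 ± 3.6 to 843 ± 41, nanog from 984 ± 8.6 to 1346 ± 20 and hdac1 from 145 ± 3.6 to 201 ± 6.5. Buc, klf17 and crebbpa fell. Crebbpb and ep300b did not pass (adjusted p = 0.117 and 0.0754). Ep300b passed with total-count scaling (0.0013), with recomputed size factors (0.0449) and without DMSO replicate 1 of 3.5 hpf (0.0314). In limma 8662 of 12354 tested genes passed, 4427 higher and 4235 lower at 4.5 hpf (3050 and 5470 with TPM, 3284 and 5175 with total-count scaling), 983 and 629 of them by more than 2-fold. Zygotic-only genes rose in 570 and fell in 17 of 654 (577 and 19 adjusted over the list alone). This class was chosen in part for its level at 4.5 hpf in these libraries, and the maternal falling class for its fall over this interval, so no set p is given for either here.

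In exposed embryos the same comparison gave smaller changes. Stm went from 0.826 ± 0.32 to 8.62 ± 2.9 FPKM and cdk5r1a from 0.594 ± 0.36 to 11.7 ± 4.5. The T-box gene tbx16 went from 6.2 ± 2.3 to 32.1 ± 7.8, and sult6b1 and mxtx1 rose by 2.20 and 2.09 on the log2 scale. Sox19b fell from 477 ± 20 to 325 ± 32, buc from 241 ± 22 to 182 ± 12, and dnajc5ga from 82.5 ± 5.3 to 51.7 ± 5.3. Hsd17b12b, prkab1a and irs4a fell by 0.60, 0.57 and 0.56 on the log2 scale. In all 1753 of 11877 genes passed in limma, 731 higher and 1022 lower at 4.5 hpf, 140 and 3 of them by more than 2-fold. The count was 1152 and 1131 without TBBPA replicate 1 or 2 of 3.5 hpf, and 1118 and 1107 without TBBPA replicate 3 or 4 of 4.5 hpf. Zygotic-only genes rose in 256 and fell in 3 of 478 (299 and 8 adjusted over the list alone), again in a class chosen in part for its level at 4.5 hpf. Vox lay at 18.9 ± 0.57 and 17.4 ± 1.1 and did not pass (adjusted p = 0.188), nor did klf17, hdac1, ep300b or crebbpb. Hdac1 passed with recomputed size factors (adjusted p = 0.0431) and without replicate 2 of 4.5 hpf (0.0423). Nanog and pou5f3 rose by 0.10 each on the log2 scale and crebbpa fell by 0.25 (adjusted p = 0.0151, 0.0199 and 0.0417), calls that single libraries decided. Nanog lost its call without replicate 1 of 3.5 hpf, and pou5f3 without that library or replicate 3 of 4.5 hpf. Crebbpa lost its call without any replicate of 3.5 hpf or replicate 1, 3 or 4 of 4.5 hpf (adjusted p up to 0.11).

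In 1 fit over the 16 libraries, with 12780 tested genes, 989 genes rose by more than 2-fold in DMSO from 3.5 to 4.5 hpf. Their median log2 change was 1.54 in DMSO and 0.40 in TBBPA, and 905 (91.5%) changed less under TBBPA by the interaction test. Of the 630 that fell by more than 2-fold, the medians were −1.19 and −0.28, and 621 (98.6%) changed less. These genes were chosen on the DMSO libraries that the test also used. With genes chosen on 2 DMSO replicates of each stage and tested against the other 2, 571 of 694 (82.3%) and 604 of 775 (77.9%) rising genes and 526 of 557 (94.4%) and 708 of 751 (94.3%) falling genes changed less (checked after the result was seen). Over 12780 genes the slope of the change in TBBPA on that in DMSO was 0.27, with a Pearson correlation across genes of 0.741. In a principal component analysis of the 16 libraries, the first component (76.7% of variance) placed DMSO at −16.5 ± 1.2 at 3.5 hpf and 61.3 ± 6.0 at 4.5 hpf, and TBBPA at −33.1 ± 3.6 and −11.8 ± 5.0.

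**Figure D4:**
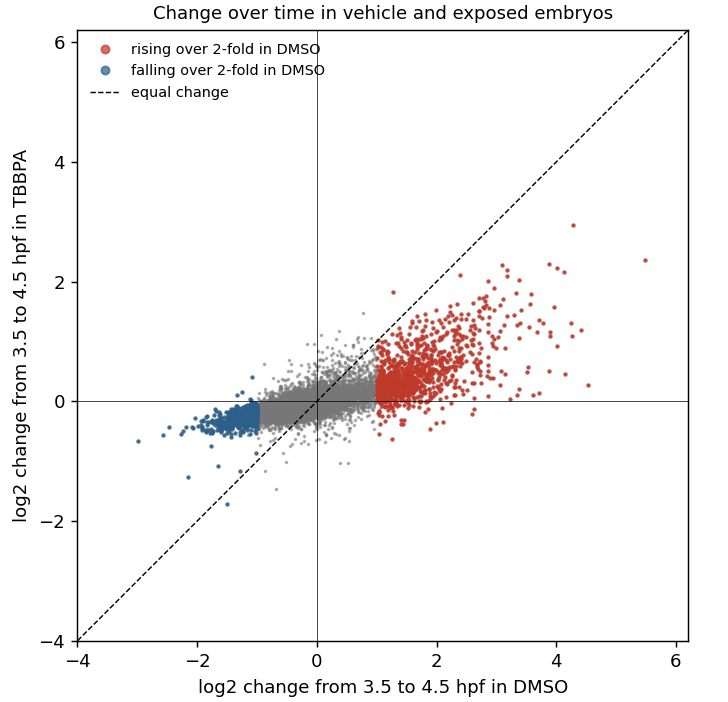
Log2 change from 3.5 to 4.5 hpf of each gene in DMSO (horizontal) and in TBBPA (vertical), with genes rising over 2-fold in DMSO in red, falling over 2-fold in blue and the others in grey; the dashed line marks equal change. The red genes have a median change of 1.54 in DMSO and 0.40 in TBBPA, and the blue ones of −1.19 and −0.28.

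The TBBPA effect differed between 4.5 and 3.5 hpf for 6753 of 12780 tested genes (limma interaction), with 3356 more positive and 3397 more negative at 4.5 hpf (4633 and 2053 with TPM, 4351 and 2284 with total-count scaling). The largest differences toward lower levels at 4.5 hpf were in krt92 (−4.25 on the log2 scale), krt4 (−3.68), capn9 (−3.57), the G protein gene gna15.1 (−3.50) and alcamb (−3.37). Those toward higher levels were in dnajc5ga (2.33), sox19b (2.01), cpeb1b (1.75), traf3 (1.75) and fam193a (1.74). All 9 enveloping layer markers, 7 endoderm markers and 4 yolk syncytial layer markers had more negative effects at 4.5 hpf, as did 65 of 76 ribosomal protein genes (camera adjusted p = 8.42e-06, 0.000243, 0.00796 and 1.42e-15; 0.254 for each with an estimated correlation; the same counts adjusted over the list alone). The p53 list was not called for a difference between the times (3 more positive and 6 more negative of 20, the same adjusted over the list alone; camera adjusted p = 0.824). Its member gadd45aa had a smaller rise at 4.5 hpf (difference −0.83). Crebbpb and ep300b did not pass (adjusted p = 0.13 and 0.162), but crebbpb passed without TBBPA replicate 1 of 3.5 hpf (0.0277), and ep300b without TBBPA replicate 4 of 3.5 hpf (0.00507) and with total-count scaling (0.0386).

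The effects at 3.5 and 4.5 hpf, which share no library, had a Pearson correlation of 0.665 and a Spearman correlation of 0.571 across 11595 genes. Of these genes 729 were higher at both times where independent calls give 276, 547 were lower at both where independent calls give 202, and 36 were called in opposite directions. The effect at 2 hpf had correlations of −0.0057 with that at 3.5 hpf and 0.032 with that at 4.5 hpf.

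The TBBPA effect at 4.5 hpf was also set against the change from 3.5 to 4.5 hpf in DMSO, gene by gene. Over 12780 genes the slope was −0.88, the Pearson correlation −0.936 and the Spearman correlation −0.943, with a covariance of −0.435. Both quantities contain the DMSO libraries of 4.5 hpf, and 100 simulated sets of unchanged groups against those libraries gave a mean correlation of −0.088 and covariance of −0.0079. With 2 of those DMSO libraries on each side the slopes were −0.95 and −0.76, the correlations −0.908 and −0.897, and the covariances −0.429 and −0.423. Genes that rise by more than 2-fold in DMSO had median effects of −1.51 and −1.26 with these splits, and genes that fall had 1.22 and 1.01.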

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

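The tests of the mitochondrial share of reads, of p53 list members above both DMSO stages and of their calls with the TBBPA libraries lowered were chosen after the results were seen, as was the rule that the spread of the p53 list members decides the verdict on slower progression. Mirror images of a split were removed from the interaction draws after a first run.

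The TBBPA effect at 4.5 hpf ran against the normal change from 3.5 to 4.5 hpf, so that genes that normally rise were low and genes that normally fall were high. With no DMSO library of 4.5 hpf on both sides the slope was −0.95 and −0.76 in the 2 ways of dividing those libraries, and a candidate explanation is slower progression of exposed embryos along the normal change. The authors' size factors, which move all genes of a library alike, are excluded as the cause, since the median effects of falling and rising genes differed by at least 2.27 on the log2 scale. In TBBPA at 4.5 hpf, 46 genes lay above both (21) or below both (25) DMSO stages by more than 2-fold and past the threshold. They were 3.14% of the 1463 called with more than 2-fold in 1 fit over the 16 libraries. By the bound set beforehand this excludes slower progression as the whole cause, but only for a delay to 3.5 hpf or later. Most genes below both were lower still at 2 hpf, such as foxd3 (6.01 FPKM, against 16.2 and 0 in DMSO at 3.5 and 2 hpf). Most genes above both also lay above their DMSO level at 2 hpf, such as cdkn1a (43.6 against 0.0785), though si:ch73-44m9.3 did not (19.8 against 50.0). Levels at 2 hpf were not tested. What stays open is how much of the effect is a delay, since no stage later or between these was sampled and developmental stage was not scored in the values.

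The p53 targets and apoptosis genes that were higher in TBBPA at 4.5 hpf (13 of 20) had a median effect of 0.64. Slower progression could not be excluded for them as a group: their median DMSO change was −0.17, with 7 of 13 falling, and members that go both ways leave the median undecided, although the bound set beforehand, a change under 0.5 of the effect, would have excluded it. The 8 of 20 tested members (40%) past the threshold above both DMSO stages were mcl1a, cdkn1a, CABZ01079011.1, phlda3, gadd45aa, sesn1, mdm2 and bbc3. Of 12760 other genes 1.5% lay so (odds ratio 43.8, one-sided Fisher's exact p = 3.22e-10 across genes, which are not independent). A level between the 3.5 and 4.5 hpf DMSO stages, and with it slower progression alone between them, is excluded for these members except mcl1a. The log2 difference of mcl1a from DMSO at 3.5 hpf was 0.145, no larger than the shift between scalings given next (0.15). With the TBBPA libraries lowered by the largest shift of the median of all genes between scalings (0.15), 11 of 13 members stayed called. For these the scaling of the libraries is excluded as the whole cause, up to a shift of that size. Casp9 and bcl2l1 lay near the threshold (limma adjusted p = 0.0391 and 0.0487). A first form of the test asked that all 13 stay called and could not decide. It was divided into these 11 and the other 2 after that outcome was seen. Scaling stays open for the other 2, whose effects no longer exceeded their errors enough. They fell from 0.14 to −0.01 (mcl1b, SE 0.036) and from 0.32 to 0.18 (bcl2a, SE 0.097). All 13 stayed called with median-of-ratios, TPM and total-count scaling. Each of these raised the median of all genes, so they could hardly remove a call and do not decide the question. The bound set beforehand for the group was not met, its median exceeding the shift of 0.15 by 0.48, less than the quartile spread of its members (1.61).

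Mitochondrially encoded transcripts were lower in TBBPA at 4.5 hpf. The share of recovered reads, which uses none of the authors' size factors, lay below all 4 DMSO libraries of 4.5 hpf in 4 of 4 TBBPA libraries, which excludes those factors as the cause. It also lay below all 4 DMSO libraries of 3.5 hpf in 4 of 4, outside the range of the sampled DMSO stages. By the rule used this excludes slower progression, but only if the normal share never falls below that range. The DMSO share was not steady, averaging 2.43%, 2.14% and 2.47% at 2, 3.5 and 4.5 hpf. A lower share at times that were not sampled would leave slower progression open. Other transcripts taking a larger share of the reads, a difference in the preparation of the libraries, and a direct effect of the exposure on mitochondria were not tested, and the share of reads in rRNA genes was also lower (0.0292% against 0.0447%).

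Other splits of the same libraries were compared with the real one. At 2 hpf the real split gave 0 genes, so that 35 of 35 splits were as large by construction (highest other 1), which decides nothing. The real split gave the most genes at 3.5 hpf (1424 genes, highest other 145, 1 of 35 splits as large) and at 4.5 hpf (8392, highest other 1, 1 of 35). So it was for the change over time in DMSO (8662, highest other 1, 1 of 35) and for that in TBBPA (1753, highest other 1, 1 of 35). A share of 1 of 35 is the smallest that these splits allow, and lies under the limit of 0.05 set beforehand. It argues against a chance assignment of these libraries. Differences between clutches or exposures, which the labels do not state, are not addressed by it. For the difference of the TBBPA effect between 4.5 and 3.5 hpf the drawn splits leave chance undecided: 5 of 100, the real one included, were as large as the real 6753, and the highest other gave 7355. The 4 other splits as large were the 4 of 99 that kept the real groups of 4.5 hpf, and with them the effect at 4.5 hpf, so they do not speak for chance either, and the highest without them gave 121.

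The TBBPA effect differed between 3.5 and 4.5 hpf by the interaction test for 6753 genes and for the following named genes, given as the log2 effect at 4.5 hpf minus that at 3.5 hpf. Of the genes with the 10 largest rises at 3.5 hpf, smaller rises were seen at 4.5 hpf in gadd45aa (−0.83), fosab (−0.93), jun (−1.13), rasl11b (−0.73) and plekhn1 (−0.94). More negative effects at 4.5 hpf were seen in krt92 (−4.25), krt4 (−3.68), cldnb (−3.10), cldne (−1.85), grhl3 (−0.59), capn9 (−3.57), gna15.1 (−3.50), alcamb (−3.37), stm (−3.12), spaca4l (−2.96), chrd (−2.46), vox (−2.20), ftr82 (−1.40), sult6b1 (−0.98), tfap2a (−0.76) and net1 (−0.67). So it was for the histone genes hist1h2a4 (−2.07) and hist2h3c (−1.21), whose near-identical copies leave their values uncertain, and for pou5f3 (−0.60), hdac1 (−0.39) and nanog (−0.35). More positive effects were seen in dnajc5ga (2.33), sox19b (2.01), cpeb1b (1.75), traf3 (1.75), fam193a (1.74), lrrcc1 (1.61), buc (1.53), buc2l (1.51), lsm1 (1.45), crebbpa (0.76) and klf17 (0.36).

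Of 184 groups of 4 libraries examined for 1 library far from the other 3, 9 held one, where chance gives 9.2. They were the recovered reads of TBBPA replicate 2 at 3.5 hpf (13.5 M), and in FPKM crebbpa in TBBPA replicate 3 (2.71) and ep300b in DMSO replicate 1 (53.6) at 2 hpf. At 3.5 hpf they were gadd45aa (1.93) and buc (191) in DMSO replicate 1 and net1 in TBBPA replicate 1 (3.33). At 4.5 hpf they were cldne (128) and cldnb (49.5) in DMSO replicate 4 and nanog in TBBPA replicate 3 (1002).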

How the results depend on the processing

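Limma voom and total-count scaling were chosen after the data were seen. Under the other pseudocounts, filters, scalings, library weights, no variance trend, 1 fit over 16 libraries and voom, each count of genes past the threshold stayed within 1.5 times its value in the report, and no call of a named gene, class or list reversed under the alternatives run for it. The number at 2 hpf was 0 in all of these. With voom it was 1564 at 3.5 hpf, 8400 at 4.5 hpf and 6581 for the difference of the effects. Leaving out each library in turn gave 925 to 1510.0 genes at 3.5 hpf, 7594 to 8033 at 4.5 hpf, 6107 to 6651 for the difference of the effects, 7841 to 8222 over time in DMSO and 1107 to 1699 over time in TBBPA. The lowest at 3.5 hpf came without TBBPA replicate 2. Over time in TBBPA the lower numbers came without TBBPA replicate 1 (1152) or 2 (1131) of 3.5 hpf, or 3 (1118) or 4 (1107) of 4.5 hpf, and the cause was not tested beyond the smaller sample.

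The difference in the zygotic-only share was −0.371 to −0.306 percentage points at 3.5 hpf and −1.80 to −1.68 at 4.5 hpf over the left-out libraries. With the replicate number as a block it was −0.337 and −1.75 with exact permutation p = 0.125, the smallest that 4 pairs allow. Whether the numbers pair the libraries is not settled: the residuals of equal numbers had correlations of −0.0824 to 0.188 across genes. The block gave 1502 genes at 3.5 hpf, 8293 at 4.5 hpf, 6863 for the difference of the effects, and 8567 (DMSO) and 1967 (TBBPA) over time. With it 2 calls of named genes were lost and 1 gained. The maternal stable class passed with an estimated correlation at 2 hpf (median log2 difference −0.0033, adjusted p = 0.00726) and with total-count scaling at 4.5 hpf (0.12, adjusted p = 0.00758), and the cause was not tested. Of 67 list tests, 27 calls were lost with an estimated correlation. These include every list call by camera that the Results give for TBBPA against DMSO at a single time. Of 1216 tests of named genes without 1 library, 27 calls were lost and 8 gained. On simulated data at the depth of these libraries, 1.5-fold changes were recovered for 47.0%, 71.2% and 59.7% of genes at 2, 3.5 and 4.5 hpf. The number of called genes there differed from that in the real fits, which moves the adjusted threshold. Smaller changes can be missed, but how often in the real fits was not measured.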

Other observations

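All of the groupings below were chosen after the data were seen. Histone genes, as annotated in the deposited tables, were lower in exposed embryos. At 3.5 hpf 35 of 72 tested fell and 1 rose (median log2 difference −0.57, camera adjusted p = 4.1e-26 over 126 families, and adjusted p = 0.0085 with an estimated correlation). At 4.5 hpf 82 of 85 fell and 2 rose (median −1.49, adjusted p = 8.5e-17 over 130 families, and 0.0466 with an estimated correlation), and with TPM scaling 80 of 84 fell (median −1.37). Of the 25 genes that lay below both DMSO stages in TBBPA at 4.5 hpf, 16 carry a histone annotation or symbol. Histone genes have near-identical copies, so the single counts are uncertain and the genes are not independent.

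C2H2 zinc finger genes, many of which lie in a cluster on chromosome 4 in zebrafish, were lower at 4.5 hpf: 287 of 427 fell and 67 rose (median −0.75, camera adjusted p = 1.9e-08, and adjusted p = 0.727 with an estimated correlation). On chromosome 4, 183 of 212 zinc finger genes fell and 15 rose (median −1.14, and −1.03 with TPM scaling). Elsewhere 104 of 215 fell and 52 rose (median −0.28), and with TPM scaling 82 of 216 fell and 63 rose (median −0.14). Other genes of chromosome 4 had a median of −0.12 that turned to 0.04 with TPM scaling. Of all tested genes of chromosome 4, 170 of 613 (27.7%) fell by more than 2-fold at 4.5 hpf against 6.37% elsewhere (Fisher's exact odds ratio 5.64, adjusted p = 1.3e-54 over 25 chromosomes). Chromosomes 25 (15.6% against 7.14%, adjusted p = 5.6e-08) and 7 (14.1% against 7.07%, 2.9e-08) also had higher shares. The falling histone genes hist2h3c and hist1h2a4 lie on chromosomes 25 and 7. Whether histone genes, with their near-identical copies, account for these shares was not tested. At 3.5 hpf the shares were 7.42% (36 of 485) against 0.703% for chromosome 4 (odds ratio 11.3, adjusted p = 4.6e-21) and 3.71% against 0.882% for chromosome 25 (0.00011). At 3.5 hpf zinc finger genes as a family had a median of −0.0026 that turned to 0.0088 with TPM scaling (camera adjusted p = 0.0064, and adjusted p = 0.989 with an estimated correlation). Those on chromosome 4 had a median of −0.34 (−0.30 with TPM scaling), with 43 of 101 lower and 3 higher, and those elsewhere a median of 0.04. Zinc finger genes of chromosome 4 have near-identical copies, and how reads that match several copies were treated is not given in the sources used here. Their single values are therefore uncertain and the genes are not independent, so the Fisher p across genes overstates the evidence.

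Between the stages, TBBPA embryos of 4.5 hpf differed from DMSO embryos of 3.5 hpf in 1182 of 12780 genes, 566 higher and 616 lower, of which 71 and 32 by more than 2-fold. The 21 genes above both DMSO stages included 6 of the p53 list, the interferon-inducible genes isg15 (72.1 FPKM in TBBPA at 4.5 hpf, against 16.6 and 4.10 in DMSO at 4.5 and 3.5 hpf) and ifit8, the apelin receptor gene aplnrb, and foxo3b, foxi1, her12, rnd3a and rnf169.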
